A study of Mus musculus with 6 samples.

How the data were processed

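RNA of mouse retina was measured on 6 dual-colour Agilent 4x44K mouse arrays, 3 for the compound SH-42 and 3 for SH-80, each against a control. Per the labels, adult male C57BL/6 mice, 12 per group, received 1 µM of a compound, or phosphate-buffered saline as the control, in the vitreous of the right eye, and retinas were taken at day 7 and pooled by 4. The labels do not say whether each array had pools of its own. At 12 mice per group and 4 retinas per pool there would be 3 control pools for 6 arrays, so control pools may have been shared, and the arrays were treated as replicates without settling this. Per the labels, the Cy3 (green) channel of every array holds the treated RNA and the Cy5 (red) channel the control RNA, and no array has the dyes exchanged.

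The scanner files hold, per the file headers, the intensity of each spot and of its local background in both channels, raw and as processed signal. They also hold a log10 ratio, which per the file headers is that of the processed red over the processed green signal. The headers name Agilent Feature Extraction 11.0.1.1, whereas the submitters' processing notes name 9.3.2.1, and which of both made the files was not settled. The deposited value table of the series holds, from its values, the log2 of processed Cy5 over processed Cy3 plus a constant per array: 99.7% of its values lay within 0.01 of that constant on each array, and the correlation across probes was 0.9997 to 0.9999. Its scale and centring were thus settled from the values, with column medians of -0.0531, -0.0606 and -0.0612 for SH-42 replicates 1 to 3 and of -0.0611, -0.0464 and -0.0754 for SH-80 replicates 1 to 3. Its direction, Cy5 over Cy3, is opposite to treated over control as the labels give the dyes, and which of both describes the RNA in each channel stays unknown.

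Median spot signals were corrected for background by normexp with an offset of 50, normalized within each array by loess, and expressed as log2 of Cy3 over Cy5, which by the labels is treated over control. Of 43020 spots that are not controls, holding 39429 probes, 26055 probes (66.1%) matched a gene symbol through the RefSeq names of the reference table, from which names alone were used. The other probes were kept under their own names. A probe was used if it was well above background in either channel on at least 3 arrays, which removed 9977 probes. Where a gene had several probes, as 5862 had, the brightest was taken. This left 24055 features, of which 15912 have a symbol, and they are called genes here. Their number of arrays, 3 per compound, limits the precision. None of the 15 pairs of arrays held identical values.

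A linear model with 1 coefficient per compound was fitted over the 6 arrays with lmFit and eBayes of limma 3.58.1 in R 4.3.3, with p-values adjusted by Benjamini-Hochberg over the genes of a comparison and a threshold of 0.05. The comparisons were SH-42 against control, SH-80 against control and SH-42 minus SH-80. All tests were two-sided. Errors are the standard errors (SE) of the model with n = 3 arrays per compound, and intervals are 95% intervals. Gene lists, 36 in all, of retinal and neighbouring cell types, stress and signalling responses, metabolism and control genes, were tested with camera at a preset correlation of 0.01, adjusted over the lists. Camera with an estimated correlation and fry were run beside it. The groups, the tests, the lists, the alternatives and the rule for named genes were fixed before the data were examined. That rule takes, per comparison, the 10 largest rises and 10 largest falls past the threshold with the same sign on every array of the compound, fills up to 5 genes by smallest p where fewer pass, adds up to 4 members of smallest p for each list described, and always includes Gfap, Rbpms, Aif1 and Vegfa. The results of 1 further gene fixed in advance are withheld and left out of the text. Where the channel behind a ratio was not above background, a bound is given in place of the fold. The R packages data.table (1.17.8) and jsonlite (2.0.0) read the files, and figures were drawn with matplotlib 3.10.9 in Python 3.11.15.

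The model was tested on simulated data with 200 of 24055 genes changed and independent normal noise, equal on all arrays for a gene. It recovered 35.8%, 80.6% and 97% of the genes given a log2 change of 0.5, 1 and 2 on SH-42 arrays, and 38.8%, 77.6% and 93.9% on SH-80 arrays. For SH-42 minus SH-80 these shares were 5.97%, 61.2% and 87.9%. The false calls numbered 5, 6 and 5 for SH-42, SH-80 and their difference. The measured arrays differed in spread, with an SD of log2 ratios from 0.157 to 0.498, so these shares may overstate the power. For lists, 1 list of 20 genes was moved by 0.5 on the simulated SH-80 arrays, with no correlation between genes. Camera at the preset correlation called that list and 1 unmoved list. Alternatives covered background correction, dye normalization, the source of the values, the probe filter, several probes per gene, the prior variance, slide and replicate number as blocks, each array left out, the threshold and the list test. The slide follows from the array barcodes: SH-42 replicates 1 and 2 shared slide 1, and SH-42 replicate 3 and all SH-80 arrays shared slide 2. The Cy5 channel alone, and slide 2 alone for the lists, were added after seeing the data.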

Results

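Expression in the mouse retina was compared 7 days after injection of SH-42 or SH-80, compounds known here by these code names, with that after the saline control. Each of the 6 arrays set a pool of 4 retinas labelled with a compound (Cy3) against a pool labelled control (Cy5). There were 3 arrays per compound, and 24055 genes were tested. Between 58.3% and 63.1% of spots were well above background in Cy3 and between 70.9% and 76.7% in Cy5, and no spot was saturated (0). Across genes, which are not independent replicates, the log ratios of SH-42 replicate 1 correlated with those of the other 5 arrays at r between -0.16 and 0.163. The remaining 10 pairs of arrays lay between 0.471 and 0.866.

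Several genes varied far more between arrays in the channel labelled control than in the channel labelled with the compound. C3, the central complement component, had a normalized log2 signal of 12.58 to 12.64 in Cy3 over the 6 arrays and of 9.735 to 14.22 in Cy5. The 14.22 was on SH-42 replicate 1, and the next highest was 11.42 on SH-42 replicate 2. Gfap, the intermediate filament of astrocytes and stressed Muller glia, spanned 0.0846 log2 units in Cy3 and 3.44 in Cy5, and the lens gene Crygc spanned 0.518 and 3.13. Over 18218 genes bright in both channels, the correlation between arrays was 0.997 to 0.999 in Cy3 and 0.947 to 0.997 in Cy5. In Cy5, pairs with SH-42 replicate 1 lay between 0.9469 and 0.9655, and all other pairs between 0.9884 and 0.9974. The median SD between arrays was 0.0561 log2 units in Cy3 and 0.149 in Cy5. All signed values below are log2 of Cy3 over Cy5, by the labels treated over control, whereas the deposited value table runs the opposite way. The direction against control is therefore not settled, and higher and lower below mean Cy3 relative to Cy5 only. If Cy5 held the treated RNA, every sign below would turn, that of SH-42 minus SH-80 included. If the Cy3 channels held 1 common RNA, both comparisons would share it and the p-values would leave out its spread. No array had the dyes exchanged, so a gene-specific effect of the dye remains in each log ratio.

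**Figure D1:**
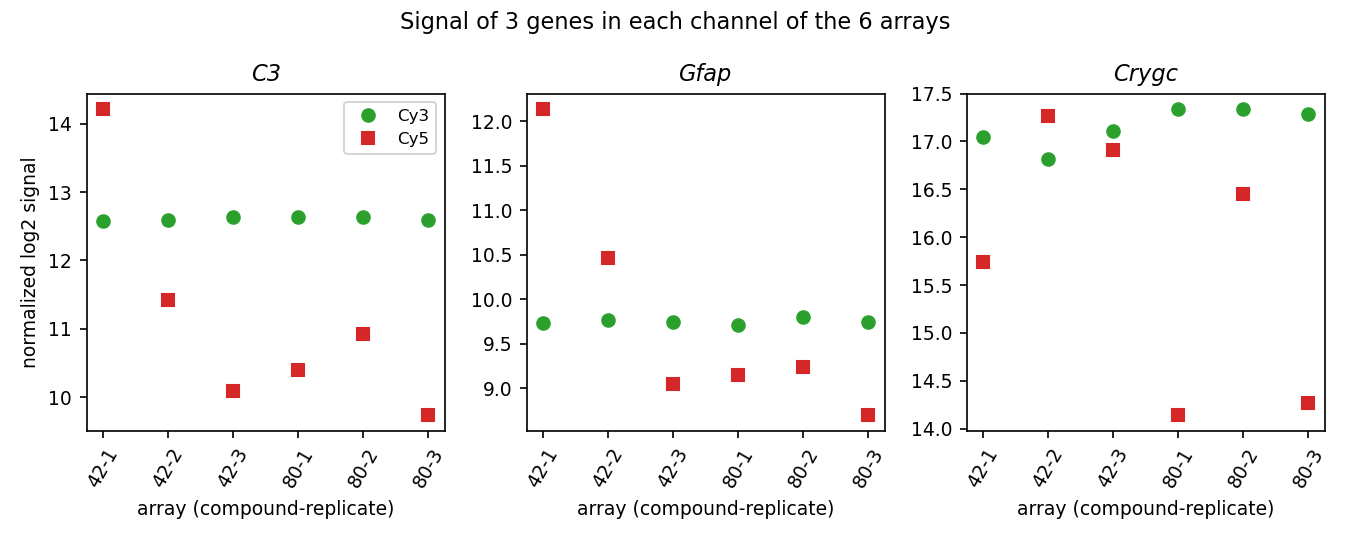
Normalized log2 signal of C3, Gfap and Crygc (vertical axes) in the Cy3 (green circles) and Cy5 (red squares) channel of each array (horizontal axes, compound and replicate). C3 lies between 12.58 and 12.64 in Cy3 and between 9.735 and 14.22 in Cy5.

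In the SH-42 arrays, Cadm4, a cell adhesion molecule, was higher in the Cy3 channel, labelled SH-42, than in the Cy5 channel, labelled control, by 0.62 ± 0.0768 (log2 ± SE, n = 3, limma adjusted p = 0.0357). The linker histone gene H1f4 was higher by 0.64 ± 0.0814, Ankrd12 by 0.64 ± 0.0622 (0.23 by its other probe) and Hcls1, an adaptor of blood cells, by 0.62 ± 0.0822. Lrp12 was higher by 0.53 ± 0.0536 and Pfkp, a phosphofructokinase of glycolysis, by 0.52 ± 0.0721 (0.18 by its other probe). Lower in Cy3 were Slc10a1, a bile acid transporter, at -0.82 ± 0.11 (adjusted p = 0.0433), and the coagulation factor F10 at -0.81 ± 0.103. Tnfrsf9, a costimulatory receptor of T cells, lay at -0.72 ± 0.0636. Zfp628 passed at -0.84 ± 0.08 by its brightest probe, but its other probe lay at -0.07. In all, 144 genes passed (limma, Benjamini-Hochberg), 13 higher and 131 lower. Of the 13, 10 also passed as higher for SH-80, and of the 131, 127 also passed as lower. Of the 144, 98 differed by at least 1.5-fold. The count depended on the processing. It was 0 with offset 0 (limma, 5294 unadjusted), 4 with scale normalization and 0 on the SH-42 arrays alone (limma, 2373 unadjusted). It was 3174 without background correction (36.6% higher), 3210 with the processed signals, 3775 with the deposited value table (29.1% higher) and 9021 with median centring (19.2% higher).

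The remaining genes named by the rule were higher for Sympk, a scaffold of mRNA end processing (0.50), and Rsrc2 (0.49), and lower for Rnu2-10 (-0.78), Spag7, Bpifc and Hecw1 (each -0.71). Zbtb44 (0.55), Spryd3 (0.49), Kctd14 (-0.84) and Knstrn (-0.77) also passed, but the probes of each of these 4 genes differ in sign. The rule required the same direction on all 3 SH-42 arrays for these largest rises and falls, so that agreement adds no support. Of the genes fixed in advance that are reported, none passed (limma adjusted p in brackets). Gfap lay at -0.31 ± 0.534 (0.73). The ganglion cell marker Rbpms, whose probes differ in sign, lay at 0.12 ± 0.0922 (0.429), the microglial marker Aif1 at -0.10 ± 0.489 (0.914), and Vegfa at -0.32 ± 0.0986 (0.158). At an unadjusted p under 0.05, 5636 genes passed, where 1203 would by chance. A dye effect can also move log ratios off 0, so the excess need not come from SH-42. In SH-42 minus SH-80, where a dye effect common to all arrays cancels, 942 genes passed at that p. The count of genes past the adjusted threshold for SH-42 was 428 (83 higher, 345 lower) without SH-42 replicate 1 and 1 without SH-42 replicate 2. It was 0 without SH-42 replicate 3 or any 1 of the SH-80 arrays, with 3032 to 4487 genes at the unadjusted p. With slide as a fixed block it was 0 (limma, 5382 unadjusted), and with slide as a random block it was 128 (10 higher, 118 lower).

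**Figure D2:**
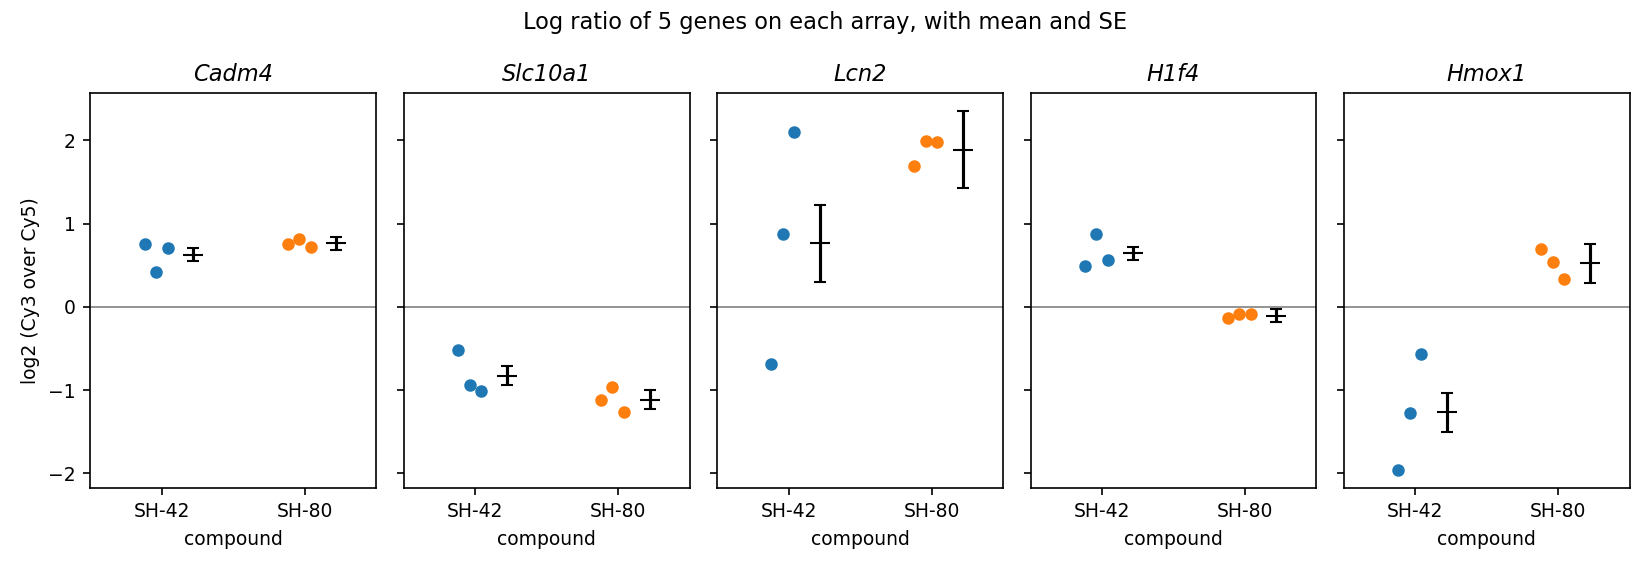
Log2 of Cy3 over Cy5 (vertical axis) of 5 genes on the 3 arrays of each compound (points, horizontal axis), with the mean and SE of the model (black). Cadm4 and Slc10a1 lie on the same side under both compounds, with means of 0.62 and -0.82 for SH-42, and Hmox1 lies below 0 on the SH-42 arrays and above 0 on the SH-80 arrays.

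As groups, the genes of several neuron types stood higher in Cy3 on the SH-42 arrays by camera with its preset correlation, while the adjusted p = 0.966 with an estimated correlation for each of the 8 lists called. For bipolar cells, 15 of 17 measured genes were positive (median 0.329, camera adjusted p = 0.0143), with Lrtm1 at 0.70 ± 0.229 and the glutamate receptor gene Grik1 at 0.53 ± 0.18. Of synapse genes, 15 of 20 were positive (median 0.181, camera adjusted p = 0.0143), with the postsynaptic scaffold Dlg4 at 0.50 ± 0.084 and the vesicle protein Vamp2 at 0.47 ± 0.116. Rod genes (20 of 25 positive, median 0.141, camera adjusted p = 0.0379) included the phosphodiesterase Pde6b at 0.67 ± 0.139 and Rp1 at 0.30 ± 0.0858 (0.11 by its other probe), but the list stood lower with arrays centred without loess (camera adjusted p = 0.0329). Amacrine genes (11 of 13 positive, median 0.235, camera adjusted p = 0.0439) included Calb2 at 0.57 ± 0.245 and Tfap2b at 0.53 ± 0.246. Lens genes were also higher (17 of 23 positive, median 0.311, camera adjusted p = 0.0181), with the crystallins Cryge at 1.60 ± 0.329 and Crygf at 1.52 ± 0.317. Sterol synthesis genes (18 of 24 positive, median 0.122, camera adjusted p = 0.0181) included Fdps at 0.45 ± 0.126 and Idi1 at 0.45 ± 0.152, and turned sign with that centring (camera adjusted p = 0.943).

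Lower was the list of other leukocytes (9 of 10 negative, median -0.245, camera adjusted p = 0.0379), with Cd3e of T cells at -0.31 ± 0.07 and Nkg7 of cytotoxic cells at -0.24 ± 0.0536. So was that of the cell cycle (19 of 19 negative, median -0.263, camera adjusted p = 0.0439), with the thymidylate synthase Tyms at -0.29 ± 0.0565 and the replication helicase Mcm4 at -0.20 ± 0.113. In these 8 lists no single member passed over all genes. Adjusted over the list alone, 1 synapse gene, 2 lens genes, 3 genes of other leukocytes and 1 cell cycle gene passed in the direction of their list, and 0 in the other 4 lists. The microglia list had 12 genes on each side (median -0.0305, mean -0.0174), while its camera test pointed higher (adjusted p = 0.867). Tyrobp lay at 0.75 ± 0.726 and Itgam, whose probes differ in sign, at -0.31 ± 0.108. The gliosis list had a median of -0.31 (camera adjusted p = 0.828), with Lcn2 at 0.76 ± 0.461 and Cntf at -0.74 ± 0.427. The ribosomal protein gene Rpl3 passed at 0.39 ± 0.0536 (limma adjusted p = 0.0497), but lay at -0.292 with arrays centred without loess. That scaling moved the median of all genes from -0.0335 to -0.245.

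SH-42 replicate 1 stood apart in these groups. List medians there were 1.06 for bipolar, 0.537 for rod, 0.969 for amacrine, 0.632 for synapse, 0.349 for sterol and 1.47 for lens genes. They were -1.65 for microglia, -1.72 for gliosis and -0.893 for cell cycle genes. Skeletal muscle genes, which are foreign to retina, had a median of -2.78 on the same array. On SH-42 replicates 2 and 3 the medians were -0.0895 and -0.0606 for bipolar cells and 0.0556 and 0.946 for microglia. For lens genes they were 0.145 and -0.605, with 12 of 23 genes below -0.5 on SH-42 replicate 3. Without SH-42 replicate 1, none of the 8 lists passed (camera adjusted p from 0.134 to 0.885), and the rod, bipolar, amacrine and cell cycle lists changed sign. Microglia (adjusted p = 2.76e-07) and gliosis (adjusted p = 0.000837) then passed as higher. The arrays behind these calls were unlike. Gliosis medians were -0.194 on SH-42 replicate 2 and 0.995 on SH-42 replicate 3, and microglia medians 0.0556 and 0.946. Without SH-42 replicate 3, by contrast, 19 lists passed, with microglia (adjusted p = 0.000511) and gliosis (adjusted p = 6.69e-05) lower. The amacrine and cell cycle lists also missed the threshold without SH-80 replicate 1 (0.0571 for each) or 3 (0.0515 for each). With slide as a fixed block none of the 8 passed (camera called 0 lists, 7 unadjusted). With an estimated correlation camera called 0 lists (0 at an unadjusted p under 0.05), and fry called 0 lists (2 unadjusted, smallest adjusted p = 0.0854).

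**Figure D3:**
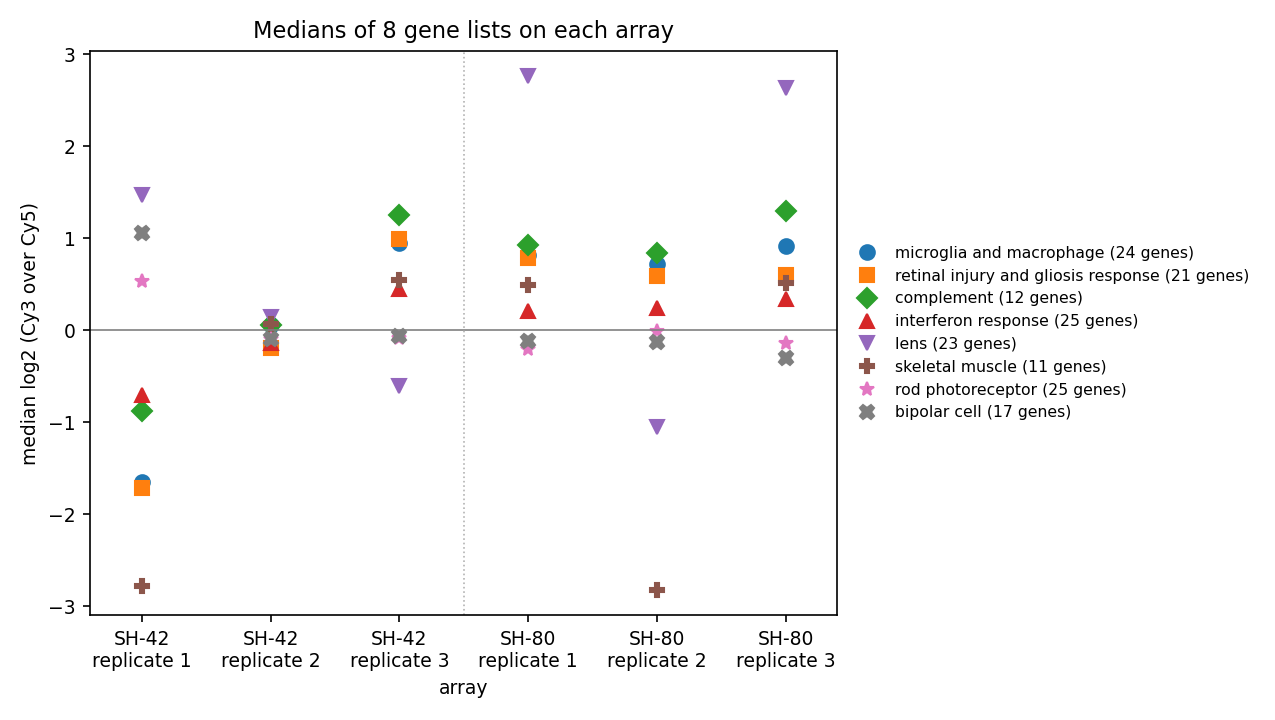
Median log2 of Cy3 over Cy5 (vertical axis) over the measured genes of 8 lists on each array (horizontal axis). The microglia list lies at -1.65 on SH-42 replicate 1 and between 0.0556 and 0.946 on the other 5 arrays, and the muscle list lies at -2.78 and -2.82 on SH-42 replicate 1 and SH-80 replicate 2.

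In the SH-80 arrays, genes of lens fibres had the highest Cy3 signal relative to Cy5. The crystallin genes Crygc (3.20 ± 0.573, log2 ± SE, n = 3, limma adjusted p = 0.029), Cryga (3.05 ± 0.454), Cryge (3.05 ± 0.329), Crygf (2.98 ± 0.317), Crygb (2.93 ± 0.419) and Crygd (2.08 ± 0.328) passed, as did the lens gene Lgsn (3.04 ± 0.492), which the lens list does not hold, and the beaded filament gene Bfsp1 (2.34 ± 0.568). Also higher were C3 (2.93 ± 0.728, adjusted p = 0.0469) and Lcn2, an iron-siderophore binding protein of the acute phase (1.89 ± 0.461, adjusted p = 0.0455). Among the lowest were Slc10a1 (-1.11 ± 0.11, adjusted p = 0.0149), Pde5a, which degrades cyclic GMP (-1.12 ± 0.139), F10 (-0.95 ± 0.103), AY074887 (-1.24 ± 0.298, but -0.42 by its other probe) and Kctd14 (-1.05 ± 0.111, but as little as -0.03 by another probe). In all, 3526 genes passed (limma, Benjamini-Hochberg), 1110 higher and 2416 lower. Of these, 482 differed by at least 1.5-fold. The count was 633 with scale normalization, 2100 with the strict probe filter and 9179 on the SH-80 arrays alone (41.8% higher).

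The other genes named by the rule had a Cy3 signal not above background, so bounds are given. Prokr1 was at least 1.85-fold lower in Cy3, Serpina6 at least 1.8-fold, Olfr996 at least 1.74-fold and Dlgap5 at least 1.19-fold. No fold is given for Sntn. For the largest rises and falls the rule required the same direction on all 3 SH-80 arrays, so that agreement adds no support. None of these genes fixed in advance passed (limma adjusted p in brackets). Gfap lay at 1.29 ± 0.534 (0.142). Rbpms, again with probes of both signs, lay at -0.07 ± 0.0922 (0.629), Aif1 at 1.05 ± 0.489 (0.18), and Vegfa at -0.30 ± 0.0986 (0.0865). At an unadjusted p under 0.05, 8533 genes passed. The count was 9334 without SH-42 replicate 1, 2246 without SH-42 replicate 2, and 0 without any 1 of the SH-80 arrays (4658 to 5926 unadjusted). With slide as a fixed block it was 0 (limma, 2978 unadjusted), and with slide as a random block it was 2369 (706 higher, 1663 lower). All SH-80 arrays shared slide 2, so the fixed block takes its slide effect from the SH-42 arrays alone.

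Camera with its preset correlation called 10 lists, all higher, while the adjusted p = 0.945 with an estimated correlation for each. The lens list led (8 of 23 measured genes passed, all higher, and 21 were positive, median 1.45, camera adjusted p = 4.38e-06). The 8 were the 6 crystallin genes and Bfsp1 above and the epithelial gene Lenep (1.45 ± 0.237). The lens list moved as a whole on SH-80 replicates 1 and 3 (medians 2.76 and 2.63) but had a median of -1.05 on SH-80 replicate 2, where the 6 gamma crystallins A to F still lay at a median of 1.86. The microglia, complement, gliosis and interferon lists had positive medians on all 3 SH-80 arrays. For microglia, 23 of 24 genes were positive (median 0.764, camera adjusted p = 0.000113), with the adaptor Tyrobp at 2.37 ± 0.726 and Tmem119 at 0.71 ± 0.22. The single gene that passed was lower, namely Itgam, an integrin of myeloid cells whose probes differ in sign, at -0.58 ± 0.108. Of complement genes (11 of 12 positive, median 1.01, camera adjusted p = 0.00147), C3 and Cfb (0.94 ± 0.231) passed as higher in Cy3. C4b lay at 1.09 ± 0.338 and Serping1 at 1.39 ± 0.476. In the gliosis list (18 of 21 positive, median 0.572, camera adjusted p = 0.00243), 3 genes passed as higher in Cy3. They were Lcn2, the cytokine gene Lif (0.79 ± 0.187) and the metalloreductase gene Steap4 (1.08 ± 0.265). Serpina3n lay at 2.54 ± 0.744. Interferon response genes (22 of 25 positive, median 0.268, camera adjusted p = 0.00254) had no member that passed, with Ifit2 at 0.28 ± 0.0931 and Oas1a at 1.09 ± 0.413. With slide as a fixed block the lens, ribosomal and sterol lists kept their call. The gliosis and interferon lists turned sign (camera adjusted p = 0.759 and 0.0427), and the other 5 missed the threshold. That block takes its slide effect from the SH-42 arrays alone, the outlying SH-42 replicate 1 included. The sign changes therefore do not come from differences among the SH-80 arrays.

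Ribosomal protein genes had 6 of 39 members higher (32 positive, median 0.111, camera adjusted p = 0.000103), among them Rpl3 (0.42 ± 0.0536), Rpl19 (0.48 ± 0.0784) and Rplp1 (0.46 ± 0.0818), but the list stood lower with arrays centred without loess (camera adjusted p = 0.0182). The median of all genes was then -0.149 and not -0.0305. Heat shock genes had 4 of 21 higher (14 positive, median 0.0877, camera adjusted p = 0.037), but turned sign with that centring (camera adjusted p = 0.461). The 4 were the chaperones and co-chaperones Hsph1 (0.36 ± 0.0605), Hspb1 (1.11 ± 0.253), Cdc37 (0.30 ± 0.0568, but -0.0505 with that centring) and Ptges3 (0.23, but -0.065, with probes of both signs). Oxidative stress genes (15 of 16 positive, median 0.252, camera adjusted p = 0.037) had no member that passed, with Gsta1 at 0.91 ± 0.361 and Gclm at 0.40 ± 0.162. Sterol synthesis genes (16 of 24 positive, median 0.0822, camera adjusted p = 0.0495) also had none, with Fdps at 0.42 ± 0.126 and Sc5d at 0.16 ± 0.0499, and turned sign with that centring (camera adjusted p = 0.96). Of pigment epithelium genes (11 of 13 positive, median 0.141, camera adjusted p = 0.0495), the opsin Rgr passed as higher in Cy3 (0.67 ± 0.169). Rpe65 lay at 0.70 ± 0.2 and Ttr at 0.81 ± 0.238. Adjusted over the list alone, 8 lens, 9 ribosomal (and 1 lower), 2 complement, 3 gliosis and 6 heat shock (and 2 lower) genes were higher. So adjusted, 1 microglia gene was lower, and 0 passed in the other 4 lists. Leaving out SH-80 replicate 1 ended the calls of the pigment epithelium (0.109), sterol (0.0757) and oxidative stress (0.107) lists. Leaving out SH-80 replicate 3 ended those of pigment epithelium (0.394), heat shock (0.0567) and oxidative stress (0.118). The sterol list was also lost without SH-80 replicate 2 (0.174) and, with pigment epithelium, without SH-42 replicate 2 (0.0535 and 0.0558). With an estimated correlation camera called 0 lists (0 unadjusted), and fry called 0 (3 unadjusted, smallest adjusted p = 0.0667).

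Between the compounds, at the same dose and day, no gene passed, and the genes of smallest p are given. Hmox1, which degrades haem and responds to oxidative stress, lay at -1.27 ± 0.238 on the SH-42 arrays and 0.52 ± 0.238 on the SH-80 arrays, with each array on the side of its compound. SH-42 minus SH-80 was -1.79 ± 0.336 (95% interval -2.60 to -0.97, limma adjusted p = 0.691). The other Hmox1 probe gave -0.39, 0.11 and a difference of -0.50. Saa3, an acute-phase serum amyloid, had a Cy5 signal not above background on the SH-80 arrays, where it was at least 2.05-fold higher in Cy3, so no size is given for its difference. It lay at -0.23 ± 0.113 on the SH-42 arrays. H1f4 differed by 0.74 ± 0.115 (0.47 to 1.02), and the chaperone Pdia3 by -0.54 ± 0.0997 (-0.78 to -0.30). Of 24055 genes, 0 passed (limma, Benjamini-Hochberg; 942 at an unadjusted p under 0.05, where 1203 would by chance). The count was also 0 in the Cy3 channel alone and the Cy5 channel alone (limma, 2231 and 870 unadjusted).

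The other genes of smallest p were Prpf40b (0.43 ± 0.0875, but 0.19 by its other probe), Dynlt3 (-0.48 ± 0.0784) and Tnpo1 (-0.51 ± 0.0782, probes of differing sign), while Oas1g, Gsdma3 and Olfr1260 had Cy3 signals not above background and get no fold. For the same genes fixed in advance the difference was -1.60 for Gfap (-3.42 to 0.23). It was 0.19 for Rbpms (-0.12 to 0.51), -1.15 for Aif1 (-2.82 to 0.53) and -0.02 for Vegfa (-0.36 to 0.32). A missed threshold does not show that the compounds act alike: 90.7% of genes had an interval within ± 1, with a median interval of ± 0.278.

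**Figure D4:**
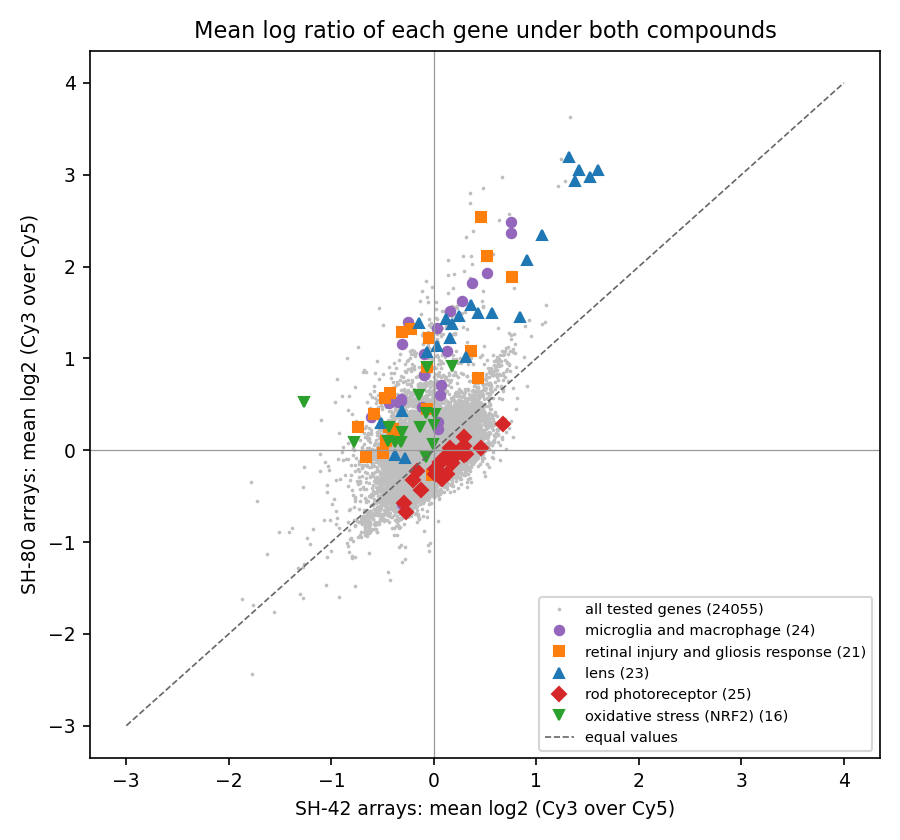
Mean log2 of Cy3 over Cy5 of each gene over the 3 SH-42 arrays (horizontal axis) and the 3 SH-80 arrays (vertical axis), with 5 lists marked in colour and a dashed line of equal values. All 23 lens genes lie above that line (median SH-42 minus SH-80 of -1.17) and all 25 rod genes lie below it (median 0.271).

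Camera with its preset correlation called 21 lists between the compounds, 7 higher and 14 lower, while the adjusted p = 0.654 with an estimated correlation (0.683 for ganglion cells). Several lists of immune and glial genes were lower in SH-42 minus SH-80, among them microglia (23 of 24 genes negative, median -0.948, camera adjusted p = 1.55e-06), with Ccl2, which attracts monocytes, at -1.65 ± 0.666 (-3.26 to -0.04) and Tmem119 at -0.64 ± 0.311. Gliosis genes (20 of 21 negative, median -0.97, camera adjusted p = 3.81e-06) included Serpina3n at -2.08 ± 1.05. Interferon genes (25 of 25 negative, median -0.422, camera adjusted p = 1.55e-06) included Ifit3 at -0.39 ± 0.184 and Oas1a at -1.06 ± 0.584. Complement genes (12 of 12 negative, median -0.927, camera adjusted p = 8.06e-05) included C4b at -1.02 ± 0.478 and Serping1 at -1.41 ± 0.674. Lens genes were lower (23 of 23 negative, median -1.17, camera adjusted p = 3.81e-06), with Crygf at -1.45 ± 0.448 (-2.54 to -0.37) and Cryge at -1.45 ± 0.465. Oxidative stress genes were lower (15 of 16 negative, median -0.494, camera adjusted p = 1.16e-05), with Hmox1 above and Nqo1 at -0.39 ± 0.211. Neuronal lists were higher. Rod genes (25 of 25 positive, median 0.271, camera adjusted p = 3.88e-05) included Pde6b at 0.39 ± 0.197 and Cngb1 at 0.31 ± 0.148. Bipolar genes (17 of 17 positive, median 0.46, camera adjusted p = 8.06e-05) included Rgs11 at 0.56 ± 0.199 and Prkca at 0.46 ± 0.226 (0.20 by its other probe). Amacrine genes (13 of 13 positive, median 0.33, camera adjusted p = 0.00134) included Pax6 at 0.29 ± 0.124 and the glycine transporter Slc6a9 at 0.33 ± 0.171. Adjusted over the list alone, 1 horizontal cell gene was higher and 1 oxidative stress gene lower. Over all genes 0 passed (limma, 942 unadjusted).

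Slide 2 held only 1 SH-42 array, replicate 3, beside the 3 SH-80 arrays, so the spread of SH-42 within it is unknown and only medians of SH-42 minus SH-80 are given. There the microglia (0.255), gliosis (0.219), interferon (0.21) and complement (0.173) lists had the opposite sign to that over all arrays. Bipolar and rod genes lay at 0.105 and 0.0407, and oxidative stress genes at -0.0103. Lens genes lay at -2.01, but their median on SH-42 replicate 3 (-0.605) was above that on SH-80 replicate 2 (-1.05). Muscle genes had a slide 2 median of 1.23, their median on SH-80 replicate 2 being -2.82. With slide as a fixed block, which also leaves 1 SH-42 array in the difference, 10 of the 21 lists turned sign and 9 others missed the threshold. Without SH-42 replicate 1, 11 lists passed (1 higher, 10 lower), and those of rod (0.198) and amacrine cells (0.38) did not. With an estimated correlation camera called 0 lists (0 unadjusted), and fry called 0 (0 unadjusted, smallest adjusted p = 0.662).

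The mean log ratios of both compounds correlated across the 24055 genes (Pearson's r = 0.536, Spearman's r = 0.551). Compounds without effect would also correlate in part if they shared a common RNA or dye effects. In simulated unchanged compounds that share their controls, the spread was split equally between treated and control pools. They gave a mean r of 0.5 (range 0.462 to 0.537 over 100 simulations). Their mean covariance was 0.0134, against 0.0342 measured. The simulated r follows from the assumed equal split, whereas the measured Cy3 signals varied less than the Cy5 signals. It therefore cannot tell what r compounds without effect would give here. Leaving out SH-42 replicate 1 gave r = 0.849 and leaving out SH-42 replicate 3 gave 0.148. Of the genes that passed, 127 were lower under both compounds, 10 were higher under both and 0 passed in opposite directions. How many would be shared by compounds without effect was not tested. Among these shared genes were Slc10a1, F10 and Tnfrsf9 on the lower side and Cadm4, Ankrd12 and Lrp12 on the higher. For 3165 genes with a pair of probes, the mean log ratio over the 6 arrays correlated between the probes at r = 0.37. The deviation of each array from that mean correlated at 0.481 to 0.786. Values shared by all arrays were thus less alike between probes of a gene than those that set arrays apart.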

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

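The tests of the red channel's noise, of SH-42 replicate 1 and of the lens genes were chosen only after the result was seen. Between the compounds, 21 gene lists differed in the test of the difference itself (camera with a preset correlation), and 0 (0 unadjusted) with an estimated correlation. The medians of SH-42 minus SH-80 were, on the lower side, -0.948 for microglia, -0.422 for interferon response, -0.97 for gliosis, -1.17 for lens, -0.114 for ribosomal protein, -0.494 for oxidative stress, -0.307 for apoptosis and p53 and -0.927 for complement genes. Also lower were immediate early (-0.276), angiogenic factor (-0.238), cell cycle (-0.277), extracellular matrix (-0.447), unfolded protein response (-0.136) and Muller glia (-0.387) genes. On the higher side the medians were 0.271 for rod, 0.46 for bipolar, 0.33 for amacrine, 0.258 for synapse, 0.313 for horizontal cell, 0.14 for circadian clock and 0.307 for ganglion cell genes. The camera adjusted p ran from 1.55e-06 for microglia to 0.0297 for ganglion cells.

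The first pattern is that the Cy3 signals were alike on all 6 arrays while the Cy5 signals varied. Noise of the red channel was argued against, since the deviations of the slide 2 arrays in Cy5 correlated at r = 0.701 between a pair of probes of the same gene, as differences in RNA would. Separately dissected pools in Cy3 were argued against too, for the tissues measured. The SD of lens, muscle and blood genes within slide 2 was 0.0264 times as large in Cy3 as in Cy5. That ratio leaves out surface epithelium genes, whose median deviation on SH-80 replicate 2 was 0.0652 in Cy3 and 1.14 in Cy5. Single genes of that list were not part of the test. The Cy3 deviations of the slide 2 arrays correlated at r = 0.0409 between a pair of probes of the same gene. This is what 1 common RNA in Cy3 predicts, but it does not show it by itself. In that case the compared pools may all lie in the Cy5 channel, opposite to the labels, and which RNA Cy3 held stays open.

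The second pattern is SH-42 replicate 1, where microglia genes lay at a median of -1.65 and gliosis genes at -1.72, opposite to the SH-80 arrays. Muscle RNA in its Cy5 pool was argued against by 1 other array, SH-80 replicate 2. There muscle genes, none of which (0 of 11) another list holds, were as low (-2.82, with Tnnc2 at -2.82 and Myl1 at -3.62). Microglia genes lay at 0.723 on it. Only 5 of the 11 muscle genes were bright in both channels on all arrays, so the shares of muscle RNA may differ. A slide effect was argued against by the difference of -1.71 between SH-42 replicates 1 and 2 on slide 1, and an action of SH-42 on every pool by the median of 0.946 on SH-42 replicate 3. On SH-42 replicate 1, microglia genes deviated from their mean over the arrays by a median of 2.06 in Cy5 and 0.0595 in Cy3. For gliosis genes these were 1.78 and 0.032. The shift thus lay in the channel labelled control, where SH-42 could act only if the dye labels were wrong. A pool with injury of its own, a wrong label or, under that condition, a different uptake of SH-42 remain as candidate explanations. No value here tested them.

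The third pattern is the lens genes, none of which (0 of 23) another list holds, with the abundant crystallins Crygc and Cryge at 3.20 and 3.05 on the SH-80 arrays. A single share of lens RNA that was higher in Cy3 was argued against, since 15 of the 23 genes lay below -0.5 on SH-80 replicate 2 while 8 lay above 0.5. Alpha and beta crystallin genes had a median of -1.61 on that array, but of 2.75 and 2.67 on SH-80 replicates 1 and 3. An action of SH-80 on them was thus not seen on every array, and 1 array cannot exclude it. For the gamma crystallins the lowest median on an SH-42 array was 0.665, so their direction was shared by all arrays and is not specific to SH-80 by sign. Over the arrays, the median deviation of lens genes ran from -0.0229 to 0.055 in Cy3 and from -1.56 to 1.53 in Cy5. The differences between arrays thus lay in the channel labelled control. A dye effect common to all arrays would not make them, and SH-80 could do so only if the dye labels were wrong. To the direction shared by all arrays, an action on the gamma crystallins and lenses of a different age or share in the RNA of the channels may contribute. So may a dye effect, and these cannot be told apart here.

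Other splits of the arrays were counted too. Exchanging arrays between the compounds gave 10 splits, too few for a share under 0.05: the real split gave 0 genes (942 unadjusted) and the highest other 0, with a count as large in 10 of 10, and 21 lists against 27 at most, with as many in 6 of 10. Any split matches a real count of 0 genes, so the 10 of 10 holds by definition. Turning the sign of single arrays gave 4 patterns per compound, also too few. For SH-42 the real pattern gave 144 genes against 0 at most (1 of 4) and 8 lists against 28 (4 of 4). For SH-80 it gave 3526 genes against 0 (1 of 4) and 10 lists against 20 (2 of 4). A dye effect of the same sign on all arrays would also lose its calls when arrays are turned. These counts of genes thus cannot tell a compound's effect from it. Exchanging SH-42 replicate 3 with SH-80 replicate 2 gave 27 lists, and the slide 2 values of the lists stand beside those of all arrays in the comparison of the compounds.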

How the results depend on the processing

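The Cy5 channel alone and, for lists, slide 2 alone were tests chosen only after the result was seen. Where no cause is named below, the cause was not tested. The count of genes for SH-42, 144 as reported (9.03% higher), was 3174 without background correction (36.6% higher), 0 with offset 0 (limma, 5294 unadjusted), and 3210 with the processed signals (31.4%). It was 9021 with median centring (19.2%), 4 with scale normalization (0%), 3775 with the deposited value table (29.1%) and 77 with the mean of a gene's probes. It was 0 on its own arrays (2373 unadjusted), 5636 at the unadjusted p (39.3%) and 0 to 428 with 1 array left out (19.4% without SH-42 replicate 1). For SH-80, 3526 as reported (31.5% higher) became 633 with scale normalization, 2100 with the strict probe filter (18223 genes tested), and 482 with a 1.5-fold limit. It was 8533 at the unadjusted p, 9179 on its own arrays (41.8%) and 0 to 9334 with 1 array left out. Where fewer SH-80 arrays were fitted, the self-test was not repeated. Without a probe filter the count was within 1.5 times, with 44.1% higher. Between the compounds it was 0 under each adjusted setting run (0 to 0 with 1 array left out, 334 to 2575 unadjusted) and 942 at the unadjusted p. Whether the replicate numbers pair the arrays is not settled. Deviations from the compound's mean correlated at -0.153, -0.431 and 0.181 between arrays of the same number, which gives no sign of pairing but cannot exclude it. With the replicate block the counts were 0 for SH-42 and 0 for SH-80 (4201 and 7147 unadjusted). Slide as a fixed block gave 0 and 0 (5382 and 2978 unadjusted), and as a random block 128 and 2369. Of lists, SH-42 had 8 (75% higher), against 3 without background correction, 4 with offset 0, 1 with scale normalization, 5 with the value table, 5 with the mean of probes and 5 with every probe (100% higher in these 6). It had 5 with a trended prior, 5 with slide as a random block, 0 with the processed signals (7 unadjusted), 0 with slide as a fixed block (7 unadjusted) and 9 with median centring (11.1% higher). There were 0 with an estimated correlation (0 unadjusted) and 0 with fry (2 unadjusted). Leaving out 1 array gave 6 to 19 (87.5% higher without SH-42 replicate 1, 42.1% without SH-42 replicate 3). SH-80 had 10 lists (100% higher), against 6 without a filter, 6 with the strict filter, and 5 with slide as a fixed block (60%). It had 0 with an estimated correlation (0 unadjusted), 0 with fry (3 unadjusted), 62.5% higher with median centring, and 7 to 14 with 1 array left out (87.5% without SH-80 replicate 1). Between the compounds, 21 lists (33.3% higher) became 5 with slide as a fixed block (60%), and 7 on slide 2 alone (57.1%). There were 0 with an estimated correlation, 0 with fry (0 unadjusted in both), and 11 to 26 with 1 array left out (9.09% without SH-42 replicate 1). Median centring gave 17.4% higher. Sign changes with median centring were, by adjusted p, SH-42 rod 0.0329 and sterol 0.943, and SH-80 heat shock 0.461, sterol 0.96 and ribosomal 0.0182. By log2 they were SH-42 Rpl3 -0.292, and SH-80 Onecut1 0.0597, Cdc37 -0.0505, Ptges3 -0.065, Ndrg1 -0.0901, Atp5c1 -0.0966 and Rps3 -0.0292, where the median of all genes had moved as given above. SH-80 gliosis (0.759) and interferon (0.0427) turned with slide as a fixed block, whose effect comes from the SH-42 arrays alone. Between the compounds, where such a block leaves SH-42 replicate 3 as the only SH-42 array in the difference, so did ganglion cell 0.512, Muller glia 0.909, gliosis 0.00508, microglia 0.308, angiogenic 0.308, unfolded protein 0.945, interferon 2.2e-05, complement 0.492, immediate early 0.909 and cell cycle 0.806. On slide 2 alone, where SH-42 had 1 array so that these p-values hold nothing of its spread, these were ganglion cell 0.105, Muller glia 0.58, gliosis 5.13e-06, microglia 7.35e-05, angiogenic 0.0643, interferon 6.45e-08, complement 0.0795, immediate early 0.731, apoptosis 0.947, cell cycle 0.36 and extracellular matrix 0.582. Without SH-42 replicate 1 the SH-42 rod, bipolar, amacrine, gliosis and cell cycle lists turned (0.134, 0.885, 0.356, 0.000837 and 0.338), as did ganglion cell and cell cycle between the compounds (0.276 and 0.784). Without SH-42 replicate 3, SH-42 microglia turned (0.000511). With 1 array left out the adjusted p for SH-42 ran from 9.69e-05 to 0.134 for rod, 5.15e-05 to 0.885 for bipolar, 0.000543 to 0.356 for amacrine and 0.000387 to 0.338 for cell cycle genes. It ran from 6.69e-05 to 0.93 for gliosis and 2.76e-07 to 0.93 for microglia, and between the compounds from 0.00418 to 0.276 for ganglion and 0.000853 to 0.784 for cell cycle genes. The correlation between compounds, 0.536, was 0.148 to 0.849 with 1 array left out and stayed within the SD of 0.366 between array pairs otherwise, at 0.452 for arrays of different replicate number. Over all settings, called genes named for SH-80 kept direction and threshold in 622 values and direction alone in 423. Those for SH-42 did so in 201 and 218, and called lists in 156 and 59 for SH-80, 90 and 80 for SH-42 and 370 and 89 between the compounds. Signal over background limits low genes, since at least 58.3% of Cy3 spots were well above it on each array and a dim channel gives a bound alone.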

Other observations

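No hypothesis was tested in this part, and its lists were fixed with the others. In the SH-80 arrays several further genes passed (limma, n = 3, same direction on each array), while their lists did not. Rose and fell here mean higher and lower in Cy3 than in Cy5. No gene differed between the compounds (limma, 0 passed), so none of these is shown to be particular to SH-80. A gene-specific dye effect common to all arrays remains in each value. Of 13 cone genes 1 rose and 1 fell: Pde6h, the inhibitory subunit of the cone phosphodiesterase, was higher (0.38 ± 0.0589, log2 ± SE, adjusted p = 0.0267) and the cone arrestin gene Arr3 lower (-0.52 ± 0.126, adjusted p = 0.0442, but -0.20 by its other probe). Among oxidative phosphorylation genes, 5 of 36 rose, such as Ndufa4 (0.48 ± 0.0747) and Atp5c1 (0.28 ± 0.0499, but -0.0966 with median centring), and Atp5j fell (-0.24 ± 0.0518); the list median was 0.0232 (camera adjusted p = 0.109). Among hypoxia targets, 3 of 23 rose, including Higd1a (0.38 ± 0.0628) and Ndrg1 (0.24 ± 0.0561, but -0.0901 with median centring), and the glycolytic regulator Pfkfb4 fell (-0.27 ± 0.0555). Glul, the glutamine synthetase of Muller glia, fell (-0.59 ± 0.116) while 12 of the 16 genes of its list were positive, and the collagen gene Col6a1 fell (-0.66 ± 0.131) while 15 of 23 matrix genes were positive. Of endothelial genes, Cldn5, a tight junction gene, rose (0.50 ± 0.126) and Pecam1 fell (-0.26 ± 0.0647). In the synapse list, whose median (0.0765) and mean (-0.00624) differed in sign, Dlg4 rose (0.41 ± 0.084) and the ribbon gene Ctbp2 fell (-0.30 ± 0.0691). The leukocyte genes Nkg7 (-0.33 ± 0.0536) and Elane (-0.28 ± 0.0474) fell, in a list with a median of -0.2 and a mean of 0.016, and 2 of 10 housekeeping genes fell, Hprt (-0.30 ± 0.069) and Gapdh (-0.51 ± 0.0814, probes of differing sign). Without any 1 of the SH-80 arrays 0 genes passed (4658 to 5926 unadjusted).

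Markers of tissues next to the retina stood apart on single arrays. Muscle genes had medians of -2.78 on SH-42 replicate 1 and -2.82 on SH-80 replicate 2, against 0.0706 to 0.551 on the other 4 arrays. Cornea and surface epithelium genes lay at -1.51 on SH-80 replicate 2, with Krt5 at -3.01 there. Blood genes lay at -0.857 on SH-42 replicate 1 and -0.985 on SH-80 replicate 3, with Hba-a2 at -1.11 and -1.25, and at 0.235 on SH-80 replicate 1. Pigment epithelium genes lay at 0.867 on SH-80 replicate 3 and 0.455 on SH-80 replicate 1, and between -0.0943 and 0.0523 on the other 4 arrays.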
